A study of Mus musculus with 12 samples.

How the data were processed

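Total RNA from mouse colon tissue was sequenced on an Illumina HiSeq instrument after extraction with TRIzol, per the labels' protocols. The labels assign the 12 libraries to 4 groups of 3 by genotype and treatment. Mice with a myeloid-specific knockout of Glul (Glul∆Lyz2) and their Glul f/f littermates each received water or DSS. The groups are named WT_H2O, KO_H2O, WT_DSS and KO_DSS here, where WT stands for the f/f littermates, and libraries carry the number in their titles, which for WT_DSS are 1, 2 and 4. Group membership came from the genotype and treatment labels alone. The labels do not state that each library is 1 animal, so the p-values measure the spread between these samples, which may be in part technical.

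The deposited log2 values of the main table are, per the labels' descriptions, log2 normalized counts with 1 column per library. The values themselves show the form log2(count divided by a factor of the library, plus 1), since 0 is the lowest value and 2 to the power of the value, minus 1, is a whole multiple of 1 step in each library. With a tolerance of 0.01, 100% of the values came out as whole multiples, so the total of reads per library and the authors' factors could be read back. Median-of-ratios factors of the recovered reads divided by the authors' factors lay between 0.883 and 0.91 in the 12 libraries, close to 1 constant. A further deposited table holds log2 FPKM plus 1 (fragments per kilobase of gene, scaled to the depth of the library) made by the authors, and served for an alternative, where changes of genes at low FPKM come out smaller. STAR as aligner and the GRCm38 and mm10 builds are named in the submitters' processing notes. The read counter, its strand setting, the gene annotation and all versions are not given in the sources used here. Another FPKM table repeated the same 12 columns to within 9e-16 and held 4 columns that match no sample label, which were used in no step.

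The count table lists 40050 genes, of which 39390 had a read in at least 1 library. Linear normalized counts were restored from the log2 values, genes with a mean normalized count of at least 10 over the 12 libraries were kept (23263 genes), and the test ran on log2(normalized count + 1). Fold changes are therefore on the scale of log2(normalized count + 1), which understates the change of low genes. Of the tested genes 1957 had no symbol in the table, and for 93.9% coordinates were taken by gene identifier from the GENCODE annotation of GRCm38, the build the notes name. Some genes share reads with a near-identical copy, such as Rn7s1 with Rn7s2, Sprr2a1 with Sprr2a2 and mt-Co3 with Gm28437, whose totals rose and fell together. Values of such genes, and of genes that overlap on the genome, are uncertain because the counting rule and strand use are unknown.

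Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), with all 12 libraries in 1 fit so that the groups shared 1 estimate of the spread. The fit left 8 residual degrees of freedom, to which eBayes added 3.86 prior ones. The comparisons were DSS against water in each genotype, knockout against f/f in each treatment, the interaction of genotype and treatment, and the knockout effect averaged over treatments. P-values were adjusted by Benjamini-Hochberg within each comparison and a gene passed at an adjusted p under 0.05. Errors of log2 changes are standard errors, and errors of group means are SDs. Glul and Lyz2 were also compared by exact two-sided permutation tests, which with 3 against 3 libraries cannot go below 0.1.

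A total of 36 gene lists for cell types and processes of the colon were fixed in advance, with 827 of 930 entries among the tested genes. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 36 lists of a comparison, then with camera at an estimated correlation and with fry. Camera compares a list with all other genes, while fry asks only whether a list's genes moved on balance 1 way. List members that passed were counted over all genes tested and again adjusted over the list alone. A list score per library is the mean log2 level of its genes relative to the mean of the 12 libraries, and list scores were compared by the same exact permutation test.

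The genes named in the text follow a fixed rule. It takes Glul and Lyz2 in each comparison. It adds the 10 genes with the most positive and the 10 with the most negative log2 change among genes that passed, had groups that did not overlap and reached a mean normalized count of 50 in the higher group, leaving out unnamed gene models and immunoglobulin and T cell receptor segments. It then takes up to 4 members of each list with the smallest p, and, where fewer than 5 passed, the 5 genes with the smallest p of the same kind, that is with a name and a mean of 50 in the higher group (and, for pairs of groups, no overlap). Some results that this rule takes are not reported. Where a group had no read of a gene in any library, the change is given as a bound against a floor of 3 reads per library. Such bounds cover counting error only.

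Depth was 14.7 to 41.2 M (mega) recovered reads per library. The whole procedure was tested on simulated data in which 200 of 23263 genes were changed by known folds and the 37 interferon response genes by 2-fold. For DSS in WT the fit recovered 55% of genes changed 4-fold and 83% of genes changed 8-fold, and for KO in DSS it recovered 59% and 85%. Of 23026 unchanged genes it called 7 in the first case and 9 in the second. Alternatives covered the FPKM table, pseudocounts, filters on low values, scaling, samples in the fit, the variance model, sample weights, the replicate number as a block, a 2-fold minimum and leaving out each library in turn. After the data had been seen, voom on the recovered reads and thinning of the reads to the total of the shallowest library were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.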

Results

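Colon RNA was profiled in mice with a myeloid-specific knockout of Glul and in Glul f/f littermates, on water or on DSS, with 3 libraries in each of the 4 groups. Glul encodes glutamine synthetase, the enzyme that makes glutamine from glutamate and ammonia. DSS is dextran sulfate sodium, a polymer that injures the colon lining and is used to induce colitis in mice. Whole tissue was sequenced, so each library mixes epithelial, immune, muscle, nerve and connective tissue cells. Libraries held 32.3 ± 4.84 M reads in WT_H2O, 35.1 ± 5.25 M in KO_H2O, 30.4 ± 0.0577 M in WT_DSS and 21.8 ± 8.34 M in KO_DSS (SD, n = 3 each). The shallowest were KO_DSS 2 with 19.8 M reads and KO_DSS 3 with 14.7 M. The 10 most abundant genes took between 10.4% and 31.6% of the reads of a library. Small structural RNAs took 7.28% ± 2.49 of reads in WT_H2O and 9.05% ± 5.34 in KO_H2O, against 2.80% ± 1.20 in WT_DSS and 2.35% ± 0.55 in KO_DSS (SD, n = 3 each). The ribosomal RNA-like genes Gm26917 and Gm42418 took 4.04% ± 0.434 in WT_H2O and 7.93% ± 5.4 in KO_H2O, and 1.83% ± 0.295 in WT_DSS and 2.16% ± 0.82 in KO_DSS (SD, n = 3 each). The median SD of log2 values within a group was 0.324 in WT_H2O, 0.399 in KO_H2O, 0.466 in WT_DSS and 0.532 in KO_DSS.

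The first principal component of the log2 values held 35.1% of the variance and placed all 6 water libraries below all 6 DSS libraries. KO_H2O 2 at -31.5 and WT_DSS 4 at 14.7 lay closest to the other treatment. The second component held 15.3% and was set by KO_DSS 3, at -169. Neither component separated the genotypes.

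**Figure D1:**
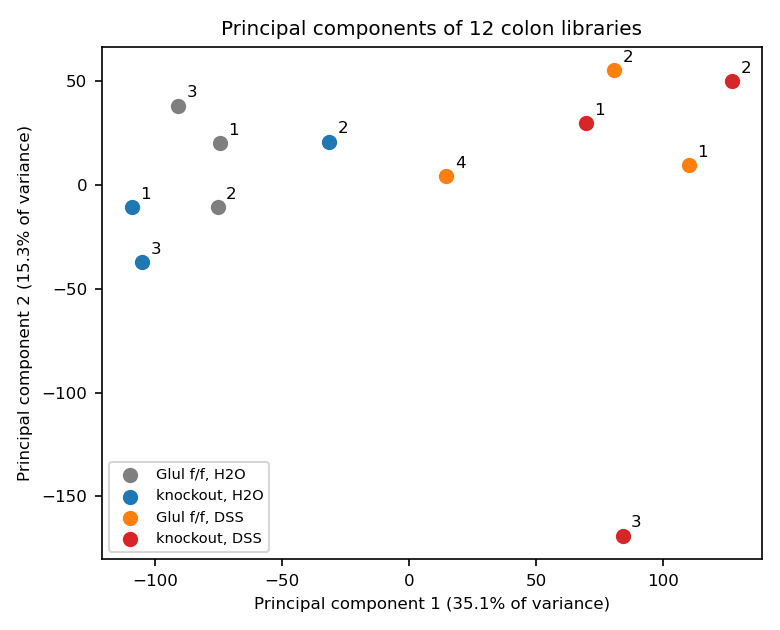
Scores of the 12 libraries on the first (x axis, 35.1% of the variance) and second (y axis, 15.3%) principal components of log2(normalized count + 1), 1 point per library, coloured by group. Water and DSS libraries lie apart on the first component, and KO_DSS 3 stands apart on the second at -169.

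The deleted gene itself was examined first. Glul (ENSMUSG00000026473, chromosome 1, 153899944 to 153909723, plus strand) was read in every library. Normalized counts were 7852, 7709 and 2261 in WT_H2O libraries 1, 2 and 3, and 1655, 5618 and 2725 in KO_H2O libraries 1, 2 and 3. They were 7372, 7895 and 18270 in WT_DSS libraries 1, 2 and 4, and 4225, 3273 and 6723 in KO_DSS libraries 1, 2 and 3. On water the knockout mean was 3333 ± 2050 against 5941 ± 3190 (SD, n = 3 each), a log2 difference of -0.81 ± 0.56 with overlapping groups (exact two-sided permutation p = 0.3). On DSS it was 4741 ± 1780 against 11180 ± 6140 (SD, n = 3 each), a log2 difference of -1.17 ± 0.56. All 3 knockout libraries lay below all 3 f/f libraries, with an exact permutation p of 0.1, the smallest that 3 against 3 can give. Averaged over treatments the log2 difference was -0.99 ± 0.40, with an exact permutation p within treatments of 0.06 where the smallest possible is 0.005. In limma no comparison of genotypes passed for Glul (adjusted p = 1 on water, 0.952 on DSS and 0.953 averaged). Lyz2 (chromosome 10, 117277331 to 117282321, minus strand), the macrophage lysozyme gene named in the knockout's label, differed between genotypes by a log2 value of 0.00 ± 0.63 on water and 0.41 ± 0.63 on DSS (exact permutation p = 1 and 0.8).

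**Figure D2:**
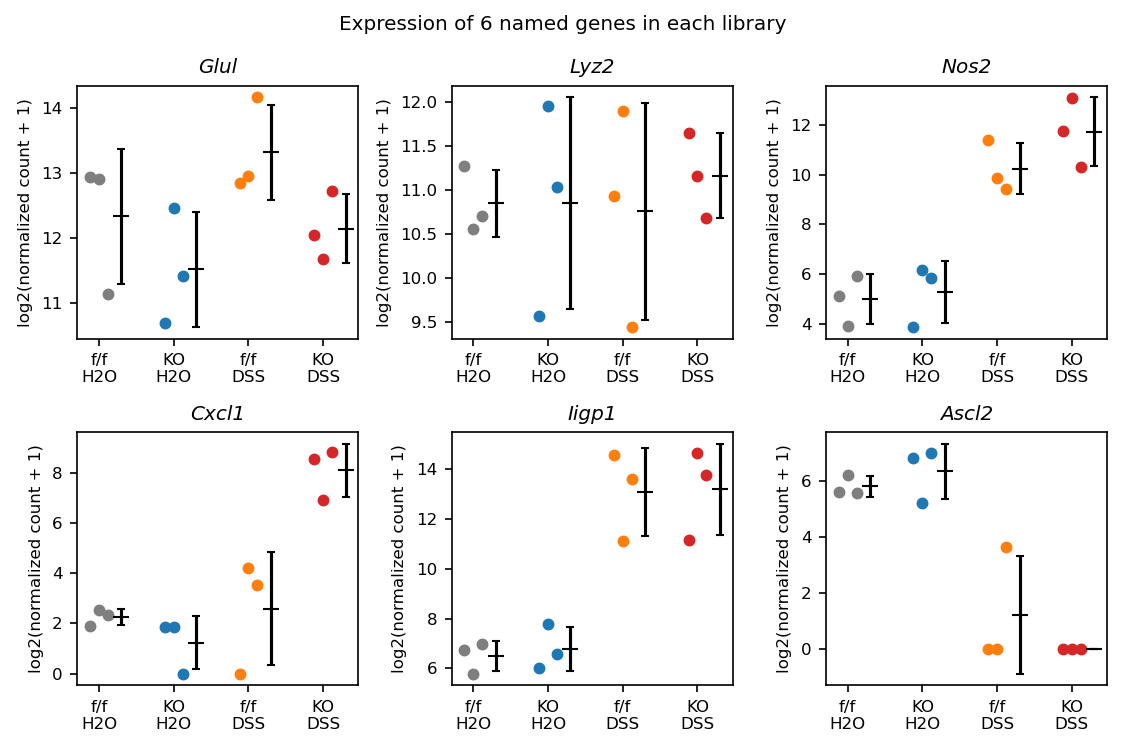
Log2(normalized count + 1) of Glul, Lyz2, Nos2, Cxcl1, Iigp1 and Ascl2 (y axes) in each library by group (x axes), with f/f for the floxed littermates, KO for the knockout, points for libraries and bars for the mean ± SD (n = 3). Glul in KO_DSS lies below WT_DSS in all 3 libraries, while the water groups overlap.

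DSS was compared with water in f/f littermates to describe the response without the knockout. Of the fixed lists, 19 of 37 interferon response genes and 4 of 16 inflammatory mediators rose and 6 of 20 epithelial stem cell genes fell, with the 3 list calls lost with an estimated correlation (adjusted p = 0.331, 0.238 and 0.311). Iigp1, an interferon-induced GTPase (chromosome 18, 60376027 to 60392634, plus strand), rose from 94.5 ± 35.9 to 12890 ± 10900 normalized counts (SD, n = 3 each), a log2 change of 6.60 ± 0.94 with adjusted p = 0.0123. Clca4b, of the chloride channel accessory family (chromosome 3, 144910921 to 144932529, minus strand), rose from 71.9 ± 39.6 to 11030 ± 8640 (SD, n = 3 each), a log2 change of 7.06 ± 0.91 with adjusted p = 0.00854. Ascl2, a transcription factor of intestinal stem cells (chromosome 7, 142966829 to 142969264, minus strand), fell from 56.2 ± 15.1 to 3.84 ± 6.66 (SD, n = 3 each), a log2 change of -4.59 ± 0.96 with adjusted p = 0.0303. Without WT_H2O 1 and without WT_H2O 2 the calls of Iigp1 (adjusted p = 0.0643 and 0.0606) and Ascl2 (0.112 and 0.106) were lost, and that of Ascl2 also without WT_H2O 3 (0.0731), WT_DSS 1 (0.0932) or WT_DSS 2 (0.0636).

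Of the 37 measured interferon response genes 19 rose and 0 fell, and 30 rose when adjusted over the list alone. All 37 had positive log2 changes, with a median of 2.59. Examples are Zbp1, a sensor of nucleic acids, with a log2 change of 3.71 ± 0.52, and the GTPase gene Irgm2 with 3.39 ± 0.48. The list passed in camera with adjusted p = 7.93e-22, and had adjusted p = 0.331 with an estimated correlation and 0.0186 in fry. Of 16 inflammatory mediators 4 rose (8 adjusted over the list alone) and the median change was 1.47, or 0.45 with the FPKM table. They were Nos2, the inducible nitric oxide synthase, with 5.21 ± 0.81, the interleukin 1 receptor antagonist gene Il1rn with 3.49 ± 0.64, Il1b with 2.46 ± 0.57 and Tnf with 2.33 ± 0.50. This list passed in camera (adjusted p = 0.00149), with adjusted p = 0.238 with an estimated correlation. Of 24 chemokine genes 2 rose (3 adjusted over the list alone). These were Cxcl10 with 4.29 ± 0.70 and Cxcl9 with 5.0 ± 1.18, both ligands that attract T cells. The chemokine list passed in camera (adjusted p = 0.0056), with adjusted p = 0.311 with an estimated correlation, and missed the threshold with a minimum mean of 50 (adjusted p = 0.0516). Of 27 antimicrobial genes 3 rose (6 adjusted over the list alone), Zbp1 and Nos2 again and Pglyrp1, a peptidoglycan binding protein, with 1.14 ± 0.27. The antimicrobial list passed in camera (adjusted p = 0.0056), with adjusted p = 0.238 with an estimated correlation. Of the 9 genes named here, 9 did not pass without WT_H2O 1 (adjusted p up to 0.132), 7 without WT_H2O 2 (0.125), 7 without WT_DSS 1 (0.132), 4 without WT_H2O 3 (0.101), 2 without KO_H2O 3 (0.0554), 2 without WT_DSS 2 (0.0919) and 1 without WT_DSS 4 (0.0685).

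Of 20 epithelial stem cell genes 6 fell and 0 rose, 11 fell when adjusted over the list alone, and the median change was -1.05. Besides Ascl2 they included Ephb3, a receptor that sorts crypt cells, with -1.93 ± 0.29, Tnfrsf19 with -1.71 ± 0.32 and the growth factor signalling inhibitor Lrig1 with -1.08 ± 0.23. The list passed in camera (adjusted p = 4.87e-06), with adjusted p = 0.311 with an estimated correlation. Of 27 goblet cell genes 3 fell (7 adjusted over the list alone), among them Slc12a8 with -2.31 ± 0.47 and Foxa3 with -1.34 ± 0.29. The goblet list passed in camera (adjusted p = 0.0408), with adjusted p = 0.81 with an estimated correlation. It did not pass without WT_H2O 1 (adjusted p = 0.166), WT_DSS 1 (0.118), WT_DSS 2 (0.0782) or KO_DSS 1 (0.0545), or with a minimum mean of 50 (0.0516). Of 26 genes of epithelial repair 2 rose (2 adjusted over the list alone), Ly6a, a marker of regenerating epithelium that blood cells also carry, with 4.02 ± 0.59 and Sprr2a3 with 1.35 ± 0.30. The repair list passed in camera (adjusted p = 0.012), with adjusted p = 0.331 with an estimated correlation. Glutamine metabolism genes, 24 measured, included 3 that fell (6 adjusted over the list alone). These were the glutamine transporter Slc1a5 with -1.34 ± 0.27, the amino acid transporter Slc7a6 with -1.68 ± 0.34 and Cad, which starts pyrimidine synthesis, with -1.08 ± 0.27. Their list did not pass in camera (adjusted p = 0.0635), with adjusted p = 0.679 with an estimated correlation and 0.0448 in fry, but passed without WT_H2O 3 (0.0459) or WT_DSS 1 (0.0142), with no filter (0.0344), quantile normalization (0.0354), upper-quartile scaling (0.0359) or sample weights (0.0455). Of the 11 genes named here, 11 did not pass without WT_H2O 1 (adjusted p up to 0.167), 11 without WT_H2O 2 (0.145), 8 without WT_DSS 1 (0.105), 7 without WT_H2O 3 (0.0827), 7 without WT_DSS 2 (0.095), 3 without WT_DSS 4 (0.0894), 2 without KO_H2O 3 (0.0684) and 1 without KO_DSS 2 (0.0509).

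Immune cell lists gave mixed results in f/f colons. The monocyte and macrophage list had 2 of 25 genes that rose (3 adjusted over the list alone), Mpeg1 with 2.16 ± 0.50 and Cybb with 2.18 ± 0.55, and passed in camera (adjusted p = 0.0275), with adjusted p = 0.822 with an estimated correlation. That call was lost without WT_H2O 2 (adjusted p = 0.0532), WT_H2O 3 (0.113) or WT_DSS 2 (0.221), with sample weights (0.212) and with a minimum mean of 50 (0.0516). The T and NK cell list (29 genes, median 1.09) and the dendritic and antigen presentation list (22 genes, median 1.04) passed in camera with no gene past the threshold, the latter with 6 higher when adjusted over the list alone and the former with 0. Adjusted p was 0.012 and 0.00466, and for both adjusted p = 0.795 with an estimated correlation. The T and NK cell call was lost without WT_H2O 2 (median 0.70, adjusted p = 0.074) or WT_DSS 4 (0.67, 0.089), with a minimum mean of 50 (0.44, 0.506) and with the replicate block (0.61, 0.121), and its median was 0.71 without WT_H2O 1. With the FPKM table the medians were 0.20 and 0.43. The neutrophil list had a median of 0.93, or 0.84 with 1 gene unread in WT_H2O set to its bound, 0.30 without WT_DSS 4, 0.03 with no filter and 1.62 with a minimum mean of 50, and did not pass here, in any other setting or without any 1 library (adjusted p = 0.338, and adjusted p = 0.866 with an estimated correlation). Of Mpeg1 and Cybb, 2 did not pass without WT_H2O 1 (adjusted p up to 0.104), 2 without WT_H2O 2 (0.147), 2 without WT_H2O 3 (0.115), 2 without KO_H2O 3 (0.0682), 2 without WT_DSS 1 (0.147), 2 without WT_DSS 2 (0.101), 1 without KO_DSS 1 (0.0579) and 1 without KO_DSS 2 (0.0506).

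Among the other genes with the most positive changes, Abca13 had no read in WT_H2O and 840.3 ± 1000 normalized counts in WT_DSS (SD, n = 3), at least 345-fold higher. Slfn1, an immune regulator gene, likewise had no read in WT_H2O and was at least 25.8-fold higher. Gbp10 (6.87 ± 1.44), Tgtp1 (6.24 ± 1.09), Ces2f (6.17 ± 1.46), Tnfrsf8 (5.48 ± 1.37) and mt-Td (6.70 ± 0.79) also rose, as did a gene overlapping Itgam and listed under its symbol (6.39 ± 1.40). Gbp10 and Tgtp1 have close paralogs, so their values are uncertain, as is that of the gene overlapping Itgam. Among the most negative changes besides Ascl2 were Slc17a2 (-5.28 ± 1.18), Rtn4r (-5.04 ± 1.16), Hapln4 (-4.85 ± 1.19), Ugt2b36 (-4.57 ± 0.99), Mal (-4.51 ± 0.97), Fat2 (-4.48 ± 1.03), Hist1h2be (-4.42 ± 0.999), Hhatl (-4.20 ± 1.06) and Snord22 (-4.17 ± 0.86). All of these passed in limma, with adjusted p between 0.00661 and 0.0464. Of the 18 genes named here, 17 did not pass without WT_H2O 1 (adjusted p up to 0.152), 17 without WT_H2O 2 (0.146), 16 without WT_DSS 1 (0.149), 14 without WT_H2O 3 (0.119), 12 without WT_DSS 2 (0.107), 9 without KO_H2O 3 (0.067), 3 without KO_H2O 1 (0.0629), 3 without WT_DSS 4 (0.0673), 2 without KO_DSS 1 (0.0561) and 1 without KO_DSS 2 (0.0524).

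Across the 23263 tested genes 503 rose and 600 fell in WT_DSS against WT_H2O, 1103 in all, of which 976 changed at least 2-fold. The groups did not overlap for 34.1% of genes, where chance gives 10%. Genes that rose made up 45.6% of those that passed and 20.9% with upper-quartile scaling, which moved the median of all genes by -0.185 on the log2 scale, so the balance of rises and falls depends on the scaling. Only 14 passed without WT_H2O 1, 27 without WT_H2O 2 and 240 without WT_H2O 3. The count was 104 without WT_DSS 1, 558 without WT_DSS 2 and 492 without KO_H2O 3. It was 664 with no filter, 3558 with sample weights and far lower with the replicate block (below). Of the 56 genes with a call here that the naming rule took, 54 did not pass without WT_H2O 1, 52 without WT_H2O 2 and 45 without WT_DSS 1, and 2, Clca4b and mt-Td, passed without any 1 library.

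DSS was then compared with water in the knockout. Of the fixed lists, 6 of 16 inflammatory mediators, 24 of 37 interferon response genes and 9 of 27 antimicrobial genes rose, while 8 of 36 lipid and xenobiotic genes fell and 2 rose, and 6 of 20 epithelial stem cell genes fell and 1 rose. With an estimated correlation the interferon (adjusted p = 0.36), lipid (0.646) and stem cell (0.455) list calls were lost. Cxcl1, a neutrophil chemokine (chromosome 5, 90891241 to 90893115, plus strand), rose from 1.75 ± 1.51 to 321.6 ± 180 normalized counts (SD, n = 3 each), a log2 change of 6.88 ± 1.05 with adjusted p = 0.00793. Nos2 (chromosome 11, 78920787 to 78960254, plus strand) rose from 47.1 ± 29.6 to 4426 ± 3750 (SD, n = 3 each), a log2 change of 6.41 ± 0.81 with adjusted p = 0.00614. Cyp4b1, a cytochrome P450 gene (chromosome 4, 115624725 to 115647723, minus strand), fell from 697.9 ± 518 to 2.15 ± 3.72 (SD, n = 3 each), a log2 change of -8.03 ± 1.21 with adjusted p = 0.00785. The call of Cyp4b1 was lost without KO_H2O 1 (adjusted p = 0.0529).

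Of the 37 interferon response genes 24 rose and 0 fell (30 rose when adjusted over the list alone), and all 37 log2 changes were positive, with a median of 2.89. Examples are Zbp1 with 4.38 ± 0.52, Cxcl10 with 5.18 ± 0.70 and Irgm2 with 3.74 ± 0.48. The list passed in camera (adjusted p = 3.16e-21), with adjusted p = 0.36 with an estimated correlation. Of 16 inflammatory mediators 6 rose (12 adjusted over the list alone), including Nos2, Il1b with 3.76 ± 0.57, Tnf with 2.71 ± 0.50 and Lif with 2.12 ± 0.42. All 16 had positive changes, with a median of 2.64, or 2.67 with 1 gene at its bound and 1.45 with the FPKM table. This list passed in camera (adjusted p = 7.8e-08) and kept its call, with adjusted p = 0.0305 with an estimated correlation. Of 27 antimicrobial genes 9 rose (14 rose and 1 fell when adjusted over the list alone), with Zbp1, Nos2, Pglyrp1 (1.51 ± 0.27) and Wfdc18 (3.29 ± 0.66) having the smallest p. The antimicrobial list passed in camera (adjusted p = 2.04e-05) and also kept its call, with adjusted p = 0.0305 with an estimated correlation. Of 24 chemokine genes 7 rose (7 adjusted over the list alone), among them Cxcl2 with 5.89 ± 1.10 and Ccl7, a monocyte attractant, with 3.99 ± 0.62. Their list passed in camera (adjusted p = 0.00039), with adjusted p = 0.126 with an estimated correlation. Of the 11 genes named here, 5 did not pass without KO_H2O 1 (adjusted p up to 0.0787) and 4 without KO_H2O 3 (0.0616).

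Of 14 neutrophil genes 6 rose (7 adjusted over the list alone), and the median change was 2.68, or 0.57 with the FPKM table and 1.78 with no filter. S100a9, a calprotectin subunit, had no read in KO_H2O and was at least 41.3-fold higher, and the receptor gene Csf3r rose by 2.57 ± 0.65, Clec4e by 4.75 ± 1.21 and Hdc by 3.39 ± 0.88. The neutrophil list passed in camera (adjusted p = 0.0011), with adjusted p = 0.372 with an estimated correlation, and did not pass with a minimum mean of 50 (adjusted p = 0.15). Monocyte and macrophage genes went both ways, with Cd14 (1.81 ± 0.49), Aif1 (1.80 ± 0.50) and Mpeg1 (1.73 ± 0.50) higher and the efferocytosis receptor Mertk (-1.46 ± 0.35) lower. That list of 25 genes (5 higher and 1 lower adjusted over the list alone) passed in camera (adjusted p = 0.018), with adjusted p = 0.765 with an estimated correlation. The call was lost without KO_H2O 1 (adjusted p = 0.0878), KO_H2O 3 (0.0804) or KO_DSS 1 (0.0716). The B and plasma cell list, 24 genes of which 0 passed over all genes or adjusted over the list alone, had a median of -2.41. It passed in camera (adjusted p = 0.00176), with adjusted p = 0.765 with an estimated correlation, and not without KO_H2O 2 (median -1.58, adjusted p = 0.0951) or with sample weights (-1.70, 0.0886), and the median was -0.73 with the FPKM table. The proliferation list had no gene past the threshold (0 of 35, also 0 adjusted over the list alone), a median of 0.74 (0.43 with upper-quartile scaling) and adjusted p = 0.00117 in camera, with adjusted p = 0.765 with an estimated correlation. Of the 8 genes named here, 8 did not pass without KO_H2O 1 (adjusted p up to 0.186), 8 without KO_H2O 3 (0.152), 7 without KO_DSS 2 (0.141), 6 without KO_DSS 1 (0.0768), 4 without WT_H2O 1 (0.0578), 3 without WT_H2O 2 (0.057), 3 without KO_DSS 3 (0.0695), 2 without WT_H2O 3 (0.059), 1 without WT_DSS 1 (0.0522) and 1 without WT_DSS 2 (0.0585).

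Of 20 epithelial stem cell genes 6 fell and 1 rose (9 and 1 adjusted over the list alone). Ascl2 had no read in KO_DSS and was at least 24.7-fold lower, and Lgr5, the crypt base stem cell marker, changed by -5.37 ± 1.23, Axin2 by -2.24 ± 0.41 and Ephb3 by -1.63 ± 0.29. The list passed in camera (adjusted p = 0.000633), with adjusted p = 0.455 with an estimated correlation. Of 26 repair genes 7 rose (11 adjusted over the list alone), including Ly6a with 3.81 ± 0.59, Sprr2a3 with 2.02 ± 0.30 and the EGF receptor ligands Ereg with 2.80 ± 0.56 and Areg with 2.26 ± 0.46. The repair list passed in camera (adjusted p = 0.00176), with adjusted p = 0.268 with an estimated correlation. Of 36 lipid and xenobiotic genes 8 fell and 2 rose (8 and 2 adjusted over the list alone), among them Cyp4b1, the glutathione transferase Gstm3 with -2.84 ± 0.50, the sulfotransferase Sult1a1 with -1.21 ± 0.24 and, higher, the cholesterol synthesis gene Hmgcs1 with 1.31 ± 0.29. This list passed in camera (adjusted p = 0.0126), with adjusted p = 0.646 with an estimated correlation. In glutamine metabolism 4 of 24 genes fell and 1 rose (4 and 2 adjusted over the list alone). The alanine transaminases Gpt2 and Gpt changed by -1.79 ± 0.26 and -3.21 ± 0.81, Slc1a5 by -1.60 ± 0.27 and the asparagine synthetase gene Asns by 1.04 ± 0.22, and the list did not pass in camera (adjusted p = 0.926, and adjusted p = 0.944 with an estimated correlation). Of the 16 genes named here, 13 did not pass without KO_H2O 1 (adjusted p up to 0.128), 7 without KO_H2O 3 (0.109), 4 without KO_DSS 2 (0.102) and 2 without KO_DSS 1 (0.0732).

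Among the other most positive changes in the knockout were Clca4b (8.72 ± 0.91), Gbp10 (7.98 ± 1.44), Cxcl5 (7.72 ± 1.78), Mmp10 (7.43 ± 1.49), Iigp1 (6.40 ± 0.94), Ly6g (6.40 ± 1.76), Olfr56 (6.28 ± 1.23) and Ido1 (6.24 ± 1.83). Olfr56 overlaps Tgtp1 on chromosome 11, so its value is uncertain. Among the most negative were Fat2 (-6.81 ± 1.03), Kcnh3 (-6.51 ± 1.62), Phospho1 (-6.04 ± 1.46) and Pbld1 (-6.04 ± 0.90). Nags, the urea cycle gene for N-acetylglutamate synthase, had no read in KO_DSS and was at least 89.4-fold lower, Cyp2w1 at least 48.2-fold lower, a copy of the small nucleolar RNA gene Rnu3b2 at least 65.2-fold lower and a gene overlapping Map2k7 and listed under its symbol at least 84.1-fold lower. All of these passed in limma, with adjusted p between 0.00317 and 0.0496. Of the 16 genes named here, 13 did not pass without KO_H2O 1 (adjusted p up to 0.159), 9 without KO_H2O 3 (0.144), 6 without KO_DSS 2 (0.16), 3 without KO_DSS 1 (0.099), 3 without KO_DSS 3 (0.0922), 2 without WT_H2O 1 (0.0701), 2 without WT_H2O 2 (0.0649), 1 without WT_H2O 3 (0.0565), 1 without KO_H2O 2 (0.109), 1 without WT_DSS 1 (0.05) and 1 without WT_DSS 4 (0.0622).

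Across the 23263 genes 1162 rose and 1328 fell in KO_DSS against KO_H2O, 2490 in all, of which 2041 changed at least 2-fold. The groups did not overlap for 31.4% of genes, where chance gives 10%. Genes that rose were 46.7% of those that passed and 13.7% with upper-quartile scaling, which moved the median of all genes by -0.314. Quantile normalization moved it by 0.154 and gave 51.9%. The number that passed was 94 without KO_H2O 1, 310 without KO_H2O 3, 831 without KO_DSS 2 and 1545 without WT_H2O 1. It was 132 with only these 6 libraries, 1590 with voom, 4936 with sample weights and lower with the replicate block. Of the 93 genes with a call here that the naming rule took, 77 did not pass without KO_H2O 1, 59 without KO_H2O 3 and 41 without KO_DSS 2, and those that passed without any 1 library included Clca4b, Cxcl1, Nos2, Il1b and Gpt2.

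DSS calls in both genotypes share 1 spread per gene, so the lists are not independent. In both, 372 genes rose and 401 fell (25.1 and 34.3 for independent lists), and 0 passed in opposite directions. Of the genes that passed in f/f mice 99.7% changed with the same sign in the knockout, and the log2 changes of all 23263 genes had a Pearson correlation of 0.684 and a Spearman correlation of 0.677 across genes, which are not independent replicates. The 773 shared genes became 11 without WT_H2O 1, 20 without WT_H2O 2, 204 without WT_H2O 3, 68 without KO_H2O 1 and 158 without KO_H2O 3. They became 82 without WT_DSS 1, 444 without WT_DSS 2, 469 without WT_DSS 4 and 386 without KO_DSS 2. The larger number of genes past the threshold in the knockout does not by itself show a larger response, and the interaction below tests the difference.

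**Figure D3:**
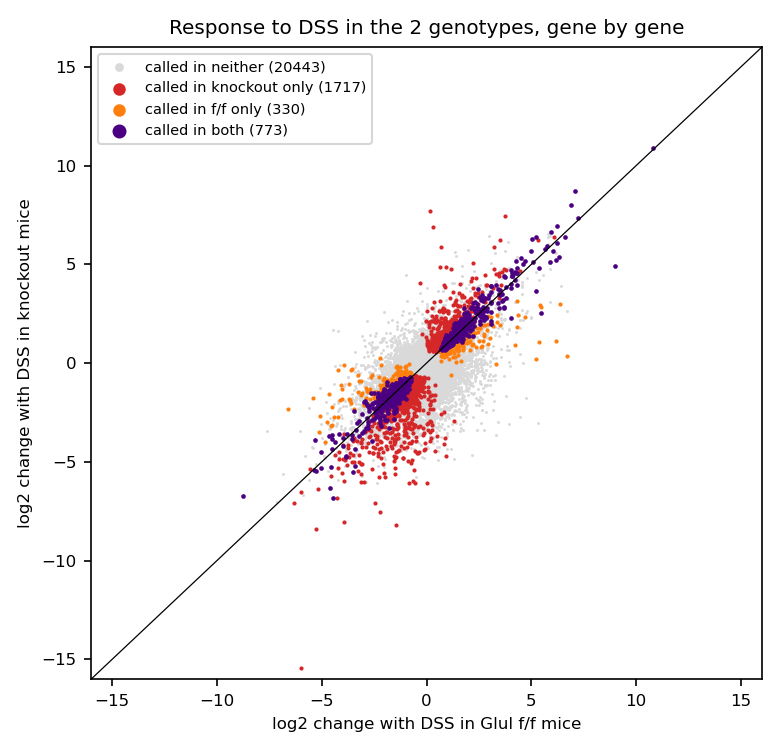
Log2 change with DSS in f/f littermates (x axis) against that in the knockout (y axis) for 23263 genes, 1 point per gene, coloured by where the gene passed. Of these, 773 passed in both, 330 in f/f littermates alone, 1717 in the knockout alone and 20443 in neither, and no gene passed in opposite directions.

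The knockout was compared with f/f littermates on water to see whether it alters the untreated colon. Of 23 fixed enteric nerve genes 22 had higher mean levels in KO_H2O, but no gene passed. The growth cone gene Gap43 differed by a log2 value of 4.05 ± 1.11, the neuronal nitric oxide synthase Nos1 by 3.05 ± 0.88 and Uchl1 by 2.64 ± 0.77, all with adjusted p = 1. Among genes of the kind the naming rule takes, the smallest p was that of Tnfsf13, which encodes the B cell factor APRIL (chromosome 11, 69682846 to 69685784, minus strand), at 132.2 ± 14.8 normalized counts in KO_H2O against 508.3 ± 77.2 in WT_H2O (SD, n = 3 each). Its log2 difference was -1.93 ± 0.36 with adjusted p = 1. Others among the 5 smallest of that kind were a gene overlapping Map2k7 and listed under its symbol (4.41 ± 0.96), Pdik1l (-1.85 ± 0.42) and Fbxl2 (1.71 ± 0.38), all with adjusted p = 1. With sample weights Tnfsf13 (adjusted p = 0.0177), the gene overlapping Map2k7 (0.0295) and Fbxl2 (0.0497) passed.

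In limma 0 of 23263 genes passed on water, with a smallest adjusted p of 0.856, and voom on recovered reads also called 0. At an unadjusted p under 0.05 there were 757 genes, 634 higher and 123 lower, 3.25% where chance gives 5%. The groups did not overlap for 9.45% of genes, where chance gives 10%, and for 0 of the 36 list scores. Most other settings called 0. The FPKM table called 2, the gene overlapping Map2k7 and MSTRG.79162, a pseudocount of 5 called MSTRG.79162 alone, and 11 passed with no filter and 16 with sample weights. Leaving out KO_H2O 3 called Pdik1l (adjusted p = 0.0295). Those genes outside the fixed rule are named after their values were seen.

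Camera at its preset correlation called 15 of 36 lists on water, and 0 with an estimated correlation and 0 in fry. Arbitrary regroupings of the same 6 libraries called up to 21 lists. Of 23 enteric nerve genes 22 had positive differences, with a median of 1.74, and 12 passed when adjusted over the list alone while 0 passed over all genes. The list had adjusted p = 2.58e-17, with adjusted p = 0.67 with an estimated correlation. Its median was 1.07 without KO_H2O 3 and 0.60 with the FPKM table, and its scores overlapped between the groups (exact permutation p = 0.2). Smooth muscle genes, the layer in which most enteric nerves lie, had a median of 0.31 that was -0.33 without WT_H2O 3, 0.11 without KO_H2O 3, 0.52 without WT_H2O 1, 0.53 without KO_H2O 1 and 0.95 without WT_H2O 2. The smooth muscle list passed in camera (adjusted p = 0.0181), with adjusted p = 0.784 with an estimated correlation, and did not pass without KO_H2O 2 (0.0532) or KO_H2O 3 (0.418), with no filter (0.0578), with only the groups compared (0.0921) or with sample weights (0.588, median 0.15), and WT_H2O 3 had the lowest score of both lists, at -2.16 for nerve and -1.34 for muscle. Nerve scores were 0.61, 0.11 and 1.82 in KO_H2O 1, 2 and 3, where the ribosomal RNA-like genes took 13.1%, 2.33% and 8.36% of reads, against 3.68% to 4.52% in WT_H2O, and mitochondrial genes took 8.36% of reads in KO_H2O 3 against 2.07% to 3.82% in the other water libraries. Medians were 1.45 for the B and plasma cell list, 0.83 for T and NK cells and 0.73 for dendritic and antigen presentation genes, with adjusted p = 0.000124, 4.73e-05 and 0.000136, and adjusted p = 0.68, 0.67 and 0.67 with an estimated correlation. Medians were -0.37 for goblet cells, -0.36 for colonocytes and -0.32 for the unfolded protein response, with adjusted p = 4.73e-05, 0.000383 and 7.38e-06, and adjusted p = 0.67 with an estimated correlation for each. Members with the smallest p were the goblet gene Agr2 (-1.26 ± 0.38, passing with sample weights at adjusted p = 0.0497) and the chaperone gene Hspa5 (-0.79 ± 0.30). Without WT_H2O 2 the B and plasma cell (median 1.11, adjusted p = 0.0838), T and NK cell (0.47, 0.0505) and dendritic (0.55, 0.0505) calls were lost, without KO_H2O 2 the B and plasma cell (0.75, 0.276) and dendritic (0.44, 0.158) calls, without WT_H2O 3 the colonocyte call (-0.031, 0.224), with a minimum mean of 50 the T and NK cell call (0.58, 0.187), and with sample weights the colonocyte call (-0.036, 0.126). With the FPKM table medians were 0.63 for B and plasma cells, 0.18 for T and NK cells and 0.42 for dendritic genes, the last 0.48 with sample weights. Medians were 2.52 for B and plasma cells and 1.15 for dendritic genes without KO_H2O 1, 1.29 for T and NK cells without WT_H2O 3 and -0.49 for the unfolded protein response without WT_H2O 2. In these 6 lists 0 genes passed over all genes or adjusted over the list alone. The glutamine metabolism list had a median of -0.07 and did not pass (adjusted p = 0.145).

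The knockout was compared with f/f littermates on DSS to see whether it alters the inflamed colon. Of 16 fixed inflammatory mediators 14 had higher mean levels in KO_DSS, but no gene passed. Cxcl1 was at 380.6, 119.6 and 464.8 normalized counts in the 3 KO_DSS libraries, against 0, 17.4 and 10.7 in WT_DSS. Its log2 difference was 5.53 ± 1.05 with adjusted p = 0.712. Differences were 5.19 ± 1.21 for S100a9, 6.66 ± 1.78 for Cxcl5, 4.47 ± 1.54 for Il11, 3.95 ± 1.51 for Il6 and 1.96 ± 0.42 for Lif, with adjusted p between 0.712 and 0.951. Among genes of the kind the naming rule takes, the smallest p was that of mt-Td, a mitochondrial tRNA gene (chromosome M, 6942 to 7011, plus strand), at 1.77 ± 1.21 in KO_DSS against 189.2 ± 91.6 in WT_DSS (SD, n = 3 each), a log2 difference of -6.05 ± 0.79 with adjusted p = 0.154. Zbtb45 (2.06 ± 0.38), Tinagl1 (1.15 ± 0.23) and Ccdc114 (-1.41 ± 0.29) followed with Cxcl1, each with adjusted p = 0.712.

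In limma 0 of 23263 genes passed on DSS, and voom on recovered reads called 0. At an unadjusted p under 0.05 there were 1215 genes, 497 higher and 718 lower, 5.22% where chance gives 5%. The groups did not overlap for 7.07% of genes, where chance gives 10%, and for 4 of 36 list scores, where chance gives 3.6. The FPKM table called 2 genes, mt-Td and Gm13056, a pseudocount of 5 called mt-Td alone, and no filter called 4, mt-Td, Clec4d, Gm12041 and MSTRG.62554. Leaving out a library called 7 genes without KO_DSS 1, 7 without KO_DSS 3 (mt-Td at adjusted p = 0.0323), 3 without KO_DSS 2, 3 without WT_DSS 4 and 1 without WT_DSS 1. Those outside the fixed rule are named after their values were seen.

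Camera at its preset correlation called 20 of 36 lists on DSS, and 0 with an estimated correlation and 0 in fry. Without WT_DSS 4 it called 12, and other splits of the same 6 libraries called up to 19. The 16 inflammatory mediators had a median of 1.46, and 1 passed adjusted over the list alone and 0 over all genes. Their list had adjusted p = 1.38e-06 (0.0648 with an estimated correlation). Its median was 0.80 without KO_DSS 3, 0.83 with the FPKM table and 0.91 with no filter. Of 27 neutrophil genes 14 were tested and 13 had positive differences, with a median of 1.60. Over the list alone 3 passed, and 0 over all genes. The list had adjusted p = 2.29e-06 (0.187 with an estimated correlation). Its median was 1.04 without KO_DSS 1 and 0.50 with the FPKM table. It did not pass with a minimum mean of 50 (median 0.996, adjusted p = 0.125). Neutrophil scores were 2.65, 0.97 and 1.88 in KO_DSS against 0.06, -0.36 and 0.11 in WT_DSS. Scores of inflammatory mediators (1.51 higher), neutrophil genes (1.90 higher) and chemokines (0.68 higher) did not overlap between the groups, nor did those of oxidative and fatty acid genes (a difference of -0.20). Each had an exact permutation p of 0.1, the smallest possible. In the chemokine list 13 of 24 genes had positive differences, with a median of 0.19 and adjusted p = 0.0458, and adjusted p = 0.466 with an estimated correlation. Its call was lost without WT_H2O 2 (0.0555), KO_H2O 1 (0.0542), KO_H2O 2 (0.0556), WT_DSS 1 (0.0718, median 0.29), WT_DSS 4 (0.276, median 0.031), KO_DSS 1 (0.125, median 0.048), KO_DSS 2 (0.124) or KO_DSS 3 (0.0791), and with a pseudocount of 0.5 (0.0636), a minimum mean of 50 (0.113, median 0.044) or the replicate block (0.165, median 0.062). Its median was 0.36 with no filter and 0.12 with upper-quartile scaling. KO_DSS 2 and KO_DSS 3 were also the shallowest libraries, and mitochondrial genes took 2.44%, 2.45% and 4.67% of reads in KO_DSS 1, 2 and 3 against 4.49% to 4.75% in WT_DSS.

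Medians were -1.04 for the T and NK cell list and -1.92 for the B and plasma cell list, both with adjusted p = 1.05e-05, and with adjusted p = 0.466 and 0.609 with an estimated correlation. Without KO_DSS 3 they were -0.54 and -1.27, and the latter was -3.06 without KO_DSS 1 and -1.27 with sample weights. With the FPKM table they were -0.19 and -0.45, and the T and NK cell median was -0.53 with the replicate block. Members with the smallest p were Cd2 (-3.61 ± 1.07) and Mzb1 (-3.70 ± 1.20). All 35 proliferation genes had positive differences, with a median of 0.46 and adjusted p = 1.05e-05, and with adjusted p = 0.696 with an estimated correlation. Without WT_DSS 2 (median 0.15, adjusted p = 0.126) or WT_DSS 4 (0.17, 0.143), or with the replicate block (0.27, 0.0588), the proliferation call was lost, and the median was 1.07 without WT_DSS 1, 0.78 without KO_DSS 1 and 0.24 without KO_DSS 2. Lipid and xenobiotic genes had a median of -0.53 (adjusted p = 1.05e-05), with adjusted p = 0.289 with an estimated correlation, and -0.35 without WT_DSS 4. Matrix remodelling genes had a median of 0.69 (adjusted p = 2.76e-05), with adjusted p = 0.466 with an estimated correlation, and did not pass without KO_DSS 3 (median 0.31, adjusted p = 0.0798), with a median of 1.05 without KO_DSS 2 and 0.45 with sample weights. Repair genes had a median of 0.40 (adjusted p = 0.000143), with adjusted p = 0.187 with an estimated correlation, and 0.62 without WT_DSS 1, 0.64 without WT_DSS 2, 0.26 without WT_DSS 4, 0.98 without KO_DSS 3 and 0.70 with sample weights. Adjusted over the list alone, 2 matrix genes were higher and 1 lipid gene lower, with 0 in the other 4 lists. Interferon response genes had a median of -0.04 and did not pass (adjusted p = 0.765), but passed as higher without WT_DSS 1 (0.42, adjusted p = 0.0062) or KO_DSS 1 (0.64, 0.000195) and as lower without WT_DSS 2 (-0.55, 0.00105) or KO_DSS 2 (-0.55, 0.00174). Glutamine metabolism genes had a median of 0.12 (adjusted p = 0.0458), with adjusted p = 0.466 with an estimated correlation. That call was lost without WT_H2O 2 (adjusted p = 0.053), WT_DSS 2 (0.156), WT_DSS 4 (0.302, median 0.068), KO_DSS 1 (0.0813, median 0.19), KO_DSS 2 (0.058, median 0.20) or KO_DSS 3 (0.254) and with a minimum mean of 50 (0.0592), the FPKM table (0.101), a pseudocount of 5 (0.0527), upper-quartile scaling (0.0861, median 0.052), sample weights (0.0756), the replicate block (0.287) or voom (0.0525), and the median was 0.27 without WT_DSS 1. Gpt2 (-0.90 ± 0.26) and Psat1 (0.94 ± 0.32) had the smallest p.

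**Figure D4:**
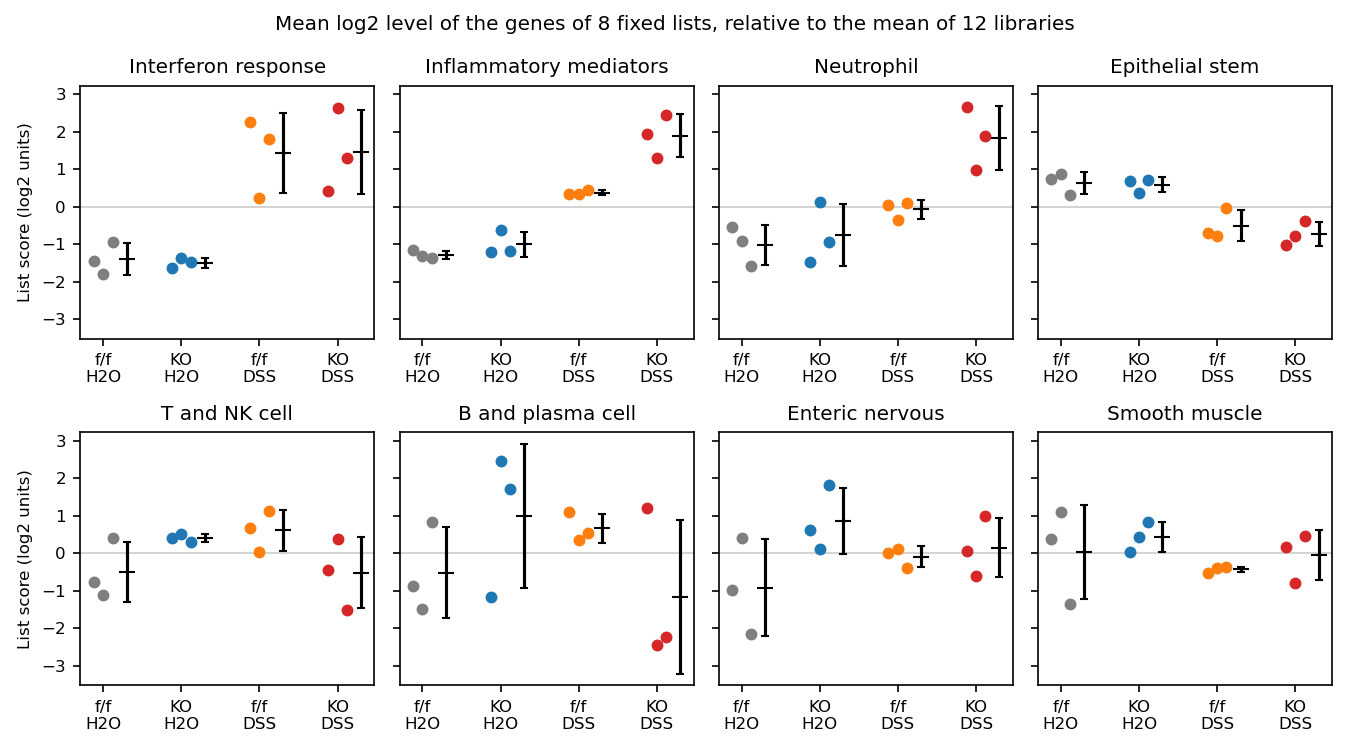
List scores (y axes, mean log2 level of a list's genes relative to the mean of the 12 libraries) of 8 fixed gene lists by group (x axes), with points for libraries and bars for the mean ± SD (n = 3). Inflammatory mediator scores lie between 1.31 and 2.44 in KO_DSS and between 0.332 and 0.461 in WT_DSS, and enteric nerve scores of the water groups overlap.

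The interaction asked whether the response to DSS differed between genotypes, and no gene passed. Cxcl1 had an interaction of 6.57 ± 1.49 on the log2 scale, Tnfrsf12a, the receptor of the cytokine TWEAK, 2.24 ± 0.51, and the lymphocyte transcription factor Ets1 -1.79 ± 0.36. Among genes of the kind the naming rule takes, the smallest p belonged to mt-Td (-6.34 ± 1.12) and the gene overlapping Map2k7 (-6.75 ± 1.36), and all 5 had adjusted p = 1. In limma 0 of 23263 genes passed, with 640 at an unadjusted p under 0.05, or 2.75%, and voom called 0. The FPKM table called 2, mt-Td and the gene overlapping Map2k7. There were 2 without KO_DSS 1 and 2 without KO_DSS 2.

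Averaged over treatments, the knockout effect also gave 0 genes in limma and 0 with voom, with 1131 at an unadjusted p under 0.05, or 4.86%. Among genes of that kind the smallest p belonged to mt-Td (-2.88 ± 0.56), Tnfsf13 (-1.29 ± 0.26), the angiotensin receptor gene Agtr1a (1.58 ± 0.32), the histone gene Hist2h3c1 (1.66 ± 0.35) and Sult1a1 (-0.78 ± 0.17), all with adjusted p = 0.953. The FPKM table called mt-Td alone. Without KO_DSS 1, 2 genes passed, without KO_DSS 2, 3 (Tnfsf13 at adjusted p = 0.0274), and without KO_DSS 3, 1. Camera called 13 of 36 lists at its preset correlation, and 0 with an estimated correlation and 0 in fry. Medians were 0.78 for inflammatory mediators (0.41 with the FPKM table, adjusted p = 1.61e-05), with adjusted p = 0.155 with an estimated correlation, and -0.45 for goblet cell genes (adjusted p = 9.56e-06), with adjusted p = 0.384 with an estimated correlation, and -0.29 without KO_H2O 2 and -0.23 with the replicate block.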

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

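Of the tests in this part, those of a single library, the share of epithelium, the muscle wall and RNA quality as sources of the patterns weighed last were chosen after the result was seen (that of epithelium in place of a first one on T and NK cells), and thinning after the data were seen. Each list given here stood out because camera, at its preset correlation, found a different response to DSS in the knockout and in f/f littermates. None of the 18 kept its call with an estimated correlation, where adjusted p lay between 0.275 and 0.86, and fry called 0. Of 100 regroupings with genotypes permuted within treatment, the real one included, 16 gave as many as the 18 lists, and the highest other count was 21, so chance cannot be excluded.

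Median interactions on the log2 scale were above 0 for neutrophil genes (1.42), inflammatory mediators (1.40), antimicrobial genes (0.54), the unfolded protein response (0.52), proliferation (0.44), immediate early and heat shock genes (0.31), ribosomal proteins (0.25) and glutamine metabolism (0.24). They were below 0 for B and plasma cells (-3.69), T and NK cells (-2.00), enteric nerves (-1.40), dendritic and antigen presentation genes (-1.10), mitochondrially encoded genes (-0.62) and endothelium (-0.58). Without WT_DSS 4, and likewise without KO_DSS 2, 11 lists were called. Called too were chemokines (0.28), epithelial junctions (0.18), hypoxia and glycolysis (0.20) and lipid and xenobiotic genes (-0.35), from which nothing is read, since with 1 library left out medians lay between 0.0037 and 0.65, 0.0063 and 0.41, 0.054 and 0.35, and -0.77 and -0.19, and calls stayed in 4, 5, 5 and 5 of 12 fits (adjusted p up to 0.303, 0.617, 0.549 and 0.283). In the other 14 lists medians that moved by over 1.5 times, or lost the call (with adjusted p in brackets) were, without WT_H2O 1, ribosomal proteins 0.13 (0.0901); without WT_H2O 2, antimicrobial genes 0.99, immediate early genes 0.29 (0.102) and mitochondrial genes -0.57 (0.102); without WT_H2O 3, ribosomal proteins 0.39 and endothelium -0.60 (0.156); without KO_H2O 1, neutrophil genes 0.90 and mitochondrial genes -1.06; without KO_H2O 2, proliferation 0.83, immediate early genes 0.18 (0.713), mitochondrial genes -0.98, ribosomal proteins 0.55 and endothelium -0.45 (0.215); without KO_H2O 3, enteric nerves -0.91, mitochondrial genes 0.24 (turned, 0.0457) and ribosomal proteins 0.00505 (0.933); without WT_DSS 1, dendritic genes -0.69, proliferation 1.13, antimicrobial genes 0.86, immediate early genes 0.52, ribosomal proteins 0.46 and mitochondrial genes -0.51 (0.175); without WT_DSS 2, glutamine metabolism 0.15, proliferation 0.17, endothelium -0.37 (0.196) and immediate early genes 0.27 (0.0734); without WT_DSS 4, proliferation 0.18, ribosomal proteins -0.0617 (0.798), glutamine metabolism 0.17 (0.0856), immediate early genes 0.28 (0.135) and mitochondrial genes -0.57 (0.125); without KO_DSS 1, proliferation 0.93, antimicrobial genes 0.93, mitochondrial genes -0.39 (0.429) and ribosomal proteins 0.0327 (0.351); without KO_DSS 2, proliferation 0.27, enteric nerves -0.79, endothelium -0.16 (0.671), unfolded protein 0.20 (0.15), immediate early genes 0.0373 (0.656), mitochondrial genes -0.47 (0.198) and ribosomal proteins 0.17 (0.0734); without KO_DSS 3, endothelium -1.06, unfolded protein 0.83, ribosomal proteins 0.47 and glutamine metabolism 0.17 (0.0681); with the FPKM table, neutrophil genes 0.50, inflammatory mediators 0.83, T and NK cells -0.38, B and plasma cells -1.16, dendritic genes -0.57, enteric nerves -0.41, endothelium -0.32 and mitochondrial genes -0.56 (0.0607); with no filter, inflammatory mediators 0.54 and mitochondrial genes -0.62 (0.0814); with a minimum mean of 50, neutrophil genes 0.33 (0.574) and antimicrobial genes 0.16 (0.11); with quantile normalization, ribosomal proteins 0.15 (0.277), glutamine metabolism 0.19 (0.0728) and immediate early genes 0.24 (0.184); with upper-quartile scaling, glutamine metabolism 0.11, immediate early genes 0.18 and ribosomal proteins 0.12; with sample weights, proliferation 0.91, mitochondrial genes -1.37, ribosomal proteins 0.82, endothelium -0.52 (0.162) and immediate early genes 0.34 (0.28); with the replicate block, proliferation 0.29, glutamine metabolism 0.18 (0.0605), immediate early genes 0.31 (0.105) and ribosomal proteins 0.18 (0.0605); with thinned reads, antimicrobial genes 0.33.

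Higher inflammatory and neutrophil genes in KO_DSS than in WT_DSS were weighed against technical explanations. Lower depth of KO_DSS 2 and KO_DSS 3 is argued against, as the inflammatory median was 1.38 after thinning to 14.7 M reads and 1.46 before. Its lowest with 1 library left out was 0.80, without KO_DSS 3, which may be part of the source. A lower share of epithelium would raise all other cell types alike. Colonocyte (median -0.39, adjusted p = 0.0211), goblet (-0.36, 0.00716) and smooth muscle lists (0.40, 0.00902) go with it only weakly (adjusted p = 0.609, 0.609 and 0.722 with an estimated correlation). Neutrophil scores were 1.90 ± 0.535 higher (SE) in KO_DSS, and 2.15 ± 0.367 minus the mean of 10 other non-epithelial cell type lists. That mean did not rise (-0.257 ± 0.211), so its subtraction cannot decide. Those calls were lost for colonocytes without WT_DSS 4 (-0.14, 0.281) or KO_DSS 2 (-0.12, 0.561), for goblet cells without WT_DSS 4 (-0.067, 0.276) or KO_DSS 3 (-0.27, 0.397), with sample weights (0.0552) or the replicate block (-0.062, 0.841), and for smooth muscle without WT_DSS 1 (0.0747), KO_DSS 1 (0.0767) or KO_DSS 3 (0.10, 0.448), where the median was 0.78 without KO_DSS 2. The 10 splits of 3 against 3 libraries are too few for a share under 0.05, with 20 lists and 0 genes in the real split and 19 lists and 60 genes in the highest others (as many lists in 1 of 10 splits and as many genes in 10 of 10, which a real 0 gives in any case). A stronger neutrophil response in the knockout may be 1 hypothesis, which neutrophil counts in colons of both genotypes at matched severity of colitis would test, though a loss of Glul did not pass in this whole tissue (adjusted p = 0.952 on DSS).

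Higher enteric nerve genes in KO_H2O than in WT_H2O were weighed in the same way, and a single library is not the whole source, since the lowest list median without 1 library was 1.07, without KO_H2O 3, against 1.74. A larger share of muscle wall in the sampled tissue was first examined by correlation, where nerve and smooth muscle scores moved together within groups over 12 libraries (Pearson r = 0.868, exact permutation p = 0.0216, Spearman 0.818, exact permutation p = 0.0193, and 0.714 and 0.685 without the 2 farthest libraries), which goes with that explanation. With the smooth muscle score as a covariate the nerve score difference was 1.35 ± 0.394 against 1.76 ± 0.722 without (SE). The score only approximates muscle wall, which may be part or all of the source. RNA quality stays open, since with the share of ribosomal RNA-like reads as a covariate the difference was 1.54 ± 0.893 (SE), less than 2 SE from 0, while it was 1.54 ± 0.674 with the mitochondrial share and 1.36 ± 0.503 with the share of small structural RNAs. The genotype stays open as a source, with splits of the 6 water libraries too few for a share under 0.05 (as many lists as the real 15 in 8 of 10, and up to 21).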

How the results depend on the processing

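Alternatives were chosen before the data were examined, except voom on recovered reads and thinning, which were chosen after seeing the data, and the cause of a change was not tested unless named. With DSS in f/f littermates 1103 genes passed, and 664 with no filter (39390 genes tested), 3558 with sample weights and 14 to 1566 when 1 library was left out, while the FPKM table (973), voom (971) and thinning (917) stayed within 1.5 times. With DSS in the knockout 2490 passed, and 132 with only the groups compared, where fewer samples set the spread, 4936 with sample weights, 1590 with voom and 94 to 3333 when 1 library was left out. Genes past the threshold in both (773) became 463 with no filter, 61 with only the groups compared, 2150 with sample weights and 11 to 1101 when 1 library was left out. For the knockout on water, 0 became 2 with the FPKM table, 1 with a pseudocount of 5, 11 with no filter and 16 with sample weights, and 0 to 1 when 1 library was left out. On DSS, 0 became 2, 1 and 4 with the FPKM table, a pseudocount of 5 and no filter, and 0 to 7 when 1 library was left out. The interaction gave 2 with the FPKM table and 0 to 2 when 1 library was left out, and the average 1 and 0 to 3. No other setting called a gene between genotypes, voom and thinning included, and no named gene that passed changed sign. Named genes past the threshold (149 over all comparisons) ranged from 69 to 166 when 1 library was left out.

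Pairing by replicate number was neither seen nor excluded. Deviations of same-numbered libraries from their group means correlated between -0.183 and 0.238 over 15 pairs, 3 of them above 0.1, and 2 of 12 libraries best with their own number. With the replicate block 46 genes passed for DSS in f/f littermates, 1411 for DSS in the knockout, 36 in both, 81 named genes and 0 in each comparison of genotypes. Lists called with the block were 13, 14, 17, 14, 13 and 14 in the 6 comparisons.

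Lists called for DSS in f/f littermates (11) became 17 with no filter, 7 with a mean of at least 50, 17 with quantile normalization, 0 with an estimated correlation and 6 with fry, and 9 to 16 when 1 library was left out. For DSS in the knockout, 14 became 2 with an estimated correlation and 7 with fry, and 12 to 19 when 1 library was left out. For the knockout on water (15), on DSS (20), the interaction (18) and the average (13), an estimated correlation and fry each gave 0. Leaving out 1 library gave 11 to 17, 12 to 21, 11 to 20 and 11 to 17. Over all 216 list tests 91 were called, 2 with an estimated correlation and 13 with fry, and 75 to 100 when 1 library was left out. The robust variance model has no list test and was run on genes alone.

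Camera's direction turned, for lists called in at least 1 of the settings compared, at the medians that follow, each with the other end of its range when 1 library was left out. With sample weights on water, monocyte and macrophage genes were at -0.42 and lipid and xenobiotic genes at 0.24. On water, fibroblast genes were at 0.062 without WT_H2O 3, and at 0.59 without KO_H2O 1. Without WT_H2O 3 smooth muscle was at -0.33 (0.95 without WT_H2O 2), oxidative genes at 0.057 (-0.22 without WT_H2O 1) and lipid and xenobiotic genes at 0.26 (-0.28 without WT_DSS 1). Monocyte and macrophage genes were at -0.32 without KO_H2O 2 (0.44 without KO_H2O 1), and without KO_H2O 3 mitochondrially encoded genes were at -0.67 (0.44 without KO_H2O 1) and ribosomal genes at 0.16 (-0.40 without KO_H2O 2). On DSS interferon genes were at -0.55 without WT_DSS 2 and -0.55 without KO_DSS 2 (0.64 without KO_DSS 1). Without KO_DSS 2 endothelial genes were at 0.30 (-0.40 without KO_DSS 3) and unfolded protein genes at -0.20 (0.34 without KO_DSS 3). Without KO_DSS 3 junction genes were at 0.24 (-0.17 without KO_DSS 1) and fibroblast genes at -0.36 (0.34 without KO_DSS 2). For the interaction smooth muscle was at -0.46 without WT_H2O 2 (0.71 without WT_H2O 3), mitochondrially encoded genes at 0.24 without KO_H2O 3 (-1.06 without KO_H2O 1) and ribosomal genes at -0.062 without WT_DSS 4 (0.55 without KO_H2O 2). For the average ribosomal genes were at -0.13 without KO_H2O 2 and -0.13 without WT_DSS 4 (0.17 without KO_H2O 3), and interferon genes at 0.26 without KO_DSS 1 (-0.35 without KO_DSS 2). With DSS in f/f littermates proliferation genes were at -0.49 without WT_DSS 1 (0.38 without WT_DSS 4). In called lists the median alone turned, without camera's direction, for dendritic genes on DSS without WT_DSS 1 (0.079), lipid and xenobiotic genes on water without KO_H2O 2 (0.0019), fibroblast genes for the average without KO_DSS 3 (-0.0003) and unfolded protein genes with DSS in the knockout without KO_DSS 2 (-0.072) or with upper-quartile scaling (-0.048).

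Depth limits low genes most in KO_DSS 2 and KO_DSS 3, where fewer reads make absent genes less certain, and thinning all libraries to the shallowest total left 2307 genes for DSS in the knockout.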

Other observations

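The tests of mt-Td in this part were chosen after its values were seen, and the regroupings before. Energy metabolism was also described by fixed lists. In knockout mice on DSS 5 of 26 hypoxia and glycolysis genes rose (8 rose and 1 fell adjusted over the list alone), among them the hexokinase gene Hk2 (2.15 ± 0.43), the glycolytic regulator Pfkfb3 (2.52 ± 0.52) and Bnip3 (1.54 ± 0.36). The list passed in camera (adjusted p = 0.00176), with adjusted p = 0.595 with an estimated correlation, and in f/f littermates it did not pass (adjusted p = 0.0635) except without WT_H2O 3 (0.00422) or KO_DSS 3 (0.0323), with no filter (0.0134) or sample weights (0.00455). Of 33 oxidative and fatty acid genes 4 fell and 1 rose in the knockout (4 and 1 adjusted over the list alone), with Acads at -2.42 ± 0.35, Acaa2 at -1.72 ± 0.32, Ppara at -2.40 ± 0.55 and, higher, Acadl at 1.95 ± 0.31. The same 4 genes passed in f/f littermates with the same signs (-1.89 ± 0.35, -1.44 ± 0.32, -2.33 ± 0.55 and 1.84 ± 0.31). That list passed in neither (adjusted p = 0.124 and 0.103), but in the knockout without KO_DSS 2 (0.0259) and in f/f littermates without WT_H2O 1 (0.0229), WT_H2O 2 (0.019) or WT_DSS 1 (0.0421), and in both with quantile normalization (0.000191 and 0.0031) or upper-quartile scaling (0.0246 and 0.0359). Of the 7 genes named here, in the knockout, 6 did not pass without KO_H2O 1 (adjusted p up to 0.109), 4 without KO_H2O 3 (0.0867), 3 without KO_DSS 2 (0.0669) and 2 without KO_DSS 1 (0.0538). Of the 4 in f/f littermates, 4 did not pass without WT_H2O 1 (adjusted p up to 0.112), 4 without WT_H2O 2 (0.0939), 4 without WT_DSS 1 (0.1), 3 without WT_H2O 3 (0.108), 2 without KO_H2O 3 (0.0569), 2 without WT_DSS 2 (0.0902) and 2 without WT_DSS 4 (0.0672).

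Among unfolded protein response genes in the knockout on DSS 6 rose and 1 fell of 25 (8 and 2 adjusted over the list alone), with Manf at 1.82 ± 0.31, Dnajb9 at 1.54 ± 0.28, Calr at 1.87 ± 0.34 and Ern2 at -1.72 ± 0.32. The 4 did not pass without KO_H2O 1 (adjusted p up to 0.0682). The list passed in camera (adjusted p = 0.0117), with adjusted p = 0.765 with an estimated correlation, and not without KO_DSS 2 (median -0.07, adjusted p = 0.269) or with quantile normalization (0.0784). Epithelial junction genes included 3 that rose and 1 that fell of 27 (6 and 1 adjusted over the list alone), with adjusted p = 0.0155 and adjusted p = 0.765 with an estimated correlation, and the call was lost without KO_H2O 2 (adjusted p = 0.101), KO_DSS 1 (0.102) or KO_DSS 2 (0.0843) and with quantile normalization (0.281). Ribosomal protein genes had a median of -0.35 with DSS in f/f littermates (adjusted p = 0.00283), with adjusted p = 0.866 with an estimated correlation, and did not pass without WT_DSS 4 (median -0.072, adjusted p = 0.335), with a median of -0.63 without WT_DSS 1, -0.52 with quantile normalization, -0.535 with upper-quartile scaling and -0.53 with sample weights. Fibroblast and collagen genes had a median of 0.32 in KO_H2O against WT_H2O (adjusted p = 0.00175), with adjusted p = 0.695 with an estimated correlation, and endothelial genes 0.45 (adjusted p = 0.000383), with adjusted p = 0.68 with an estimated correlation. Both calls were lost without KO_H2O 2 (medians 0.20 and 0.31, adjusted p = 0.304 and 0.125) and with sample weights (0.12 and 0.22, adjusted p = 0.588 and 0.306). The endothelial median was 0.29 without WT_H2O 3 and 0.24 with the FPKM table, and the fibroblast one 0.56 without WT_H2O 2, 0.59 without KO_H2O 1 and 0.062 without WT_H2O 3, where the call was lost and camera's direction turned (adjusted p = 0.896). Alternatively activated macrophage genes had a median of 0.35 in KO_DSS against WT_DSS (adjusted p = 0.0458), with adjusted p = 0.633 with an estimated correlation, and did not pass without WT_H2O 2 (adjusted p = 0.053), WT_DSS 1 (0.0922), WT_DSS 4 (0.269), KO_DSS 1 (0.643) or KO_DSS 3 (0.247), or with a pseudocount of 0.5 (0.0531), a minimum mean of 50 (0.33, median 0.23) or the replicate block (0.165). The median was 0.53 without WT_DSS 2, 0.23 without WT_DSS 4, 0.14 without KO_DSS 1 and 0.83 without KO_DSS 2. Immediate early and heat shock genes had 0.40 (adjusted p = 0.000287) and mitochondrially encoded genes -0.58 (adjusted p = 0.0131), with adjusted p = 0.466 and 0.722 with an estimated correlation. Without KO_DSS 2 both were lost (medians 0.078 and -0.42, adjusted p = 0.273 and 0.154), and the mitochondrial call also without WT_DSS 1 (0.121), WT_DSS 4 (0.0615) or KO_DSS 1 (0.365, median -0.35), with a median of -0.89 with the replicate block. In none of the 6 comparisons did camera at its preset correlation call the lists of mast cells and eosinophils, enteroendocrine and tuft cells, adipocytes, mesothelium and other tissues, red cells, circadian genes or sex-linked genes, with a smallest adjusted p of 0.0635, though a left-out library or a setting called those of adipocytes, mesothelium, red cells, circadian and sex-linked genes at least once (adjusted p down to 0.0134).

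The gene mt-Td, a mitochondrial tRNA gene, was read at 207.8, 89.7 and 270.1 normalized counts in the WT_DSS libraries and at 3.13 or lower in each library of the other groups. More mitochondrial RNA in WT_DSS would raise the other mitochondrial tRNA genes too, yet the median difference of the other 18, KO_DSS minus WT_DSS, was -0.18 against -6.05 for mt-Td. Reads assigned to 1 of several overlapping features in some libraries may be a source, since 1 other mitochondrial tRNA gene, mt-Ts2, also switched between near 0 and high counts within a group. Chance could also be one, since 7 genes were at or below 5 in 9 libraries and at or above 50 in the other 3, 1 of them in a set that is a group, where 4 of 220 sets are groups (one-sided exact binomial p = 0.121, with the limit of 5 and the binomial form set after a lower limit had missed mt-Td). No biological explanation was tested for it.

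Other splits of the libraries bear on the counts of genes and lists. For DSS against water, 1 of 10 splits gave as many genes as the real 1103 in f/f littermates, with 1 gene in the highest other, and 1 of 10 as many as the real 2490 in the knockout, with 2 in the highest other. As many lists as the real 11 came in 8 of 10 splits, with up to 17, and as many as the real 14 in 7 of 10, with up to 17. For the knockout on water, where the real count of genes is 0, other splits gave up to 29, and as many as 0 came in 10 of 10 by definition, which tests nothing. In all of these 3 against 3 libraries give too few splits for a share under 0.05. With genotypes permuted within treatment, regroupings gave up to 19 genes for the interaction and up to 100 for the average, where at least the real 0 comes in 100 of 100 by definition, which tests nothing, and 55 of 100 gave as many as 13 lists for the average (up to 21), so chance cannot be excluded for those lists. The difference of 1387 between the counts of genes that responded to DSS in the knockout and in f/f littermates was matched by 54 of 100 regroupings, with up to 5158, so chance cannot be excluded as its source. The 5158, like the 29 and 60 genes of other splits where the genotypes gave 0, is the highest of the regroupings tried. Whether such values reflect a structure of the samples was not tested.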
